A study of Mus musculus with 5 samples.

How the data were processed

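Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in 5 libraries of sorted mouse thymocytes. Per the labels' protocols, 40000 cells were sorted for each library. γδ T thymocytes were sorted as CD24+ cells with high or with low to absent CFP. CFP reports the expression of the Sox13 gene, so these fractions are called SOX13hi and SOX13lo. Both fractions were taken from TCRbeta knockout reporter animals with and without a Sox13 transgene, and double-positive (DP) thymocytes were taken from wild-type animals. The fraction names refer to the CFP sort alone. SOX13 itself, including any made from the transgene, was not measured here. Each of the 5 groups holds 1 library.

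The authors deposited 1 peak list per library, with no header, giving for each peak a chromosome, a start, an end, a name, a whole-number score and a constant strand. Coordinates are on mm9, per the submitters' processing notes. The aligner, the peak caller, its threshold, the read filters and the read depth are not given in the sources used here. What the deposited score counts is not stated by any label or file, so it was used to rank and filter peaks within a list and was never compared between lists. The read depth behind each value is therefore unknown, and a longer list can come from a deeper library as well as from more open chromatin. The name field of the SOX13lo list reads SOX13hi on every line. That of the SOX13hi list also reads SOX13hi, and those of the transgenic and DP lists match their labels. The sample's label was followed. The labels give the same index sequence for the transgenic SOX13hi and DP libraries, and no sequencing batch is given in the sources used here.

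Peaks were taken as deposited. A peak counted as shared when it met a peak of the other list by at least 1 bp. The share expected by chance was the mean over 20 random circular shifts of the first list along each chromosome. All 5 lists were also merged into regions, joining peaks that overlapped by at least 1 bp, and a region was present in a library when one of its peaks met it. Regions were counted in 100 kb windows, by their centre. For a pair of libraries the scaled difference of a window was its regions in the first library minus its regions in the second times the ratio of the totals. For γδ T cells against DP the mean of the 4 γδ libraries was used. The windows named are the 5 with the largest scaled difference in each direction, for SOX13hi against SOX13lo, transgenic against non-transgenic cells of each fraction, and γδ T cells against DP. This rule, the comparisons and the main alternatives were fixed before the data were examined. Any other region named was chosen after its values were seen, and is said to be.

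With 1 library per group no comparison has a replicate check, so no p-value is given. Intervals on shares are exact Clopper-Pearson 95% intervals, and intervals on numbers of regions in a window are exact Poisson 95% intervals. They cover counting error only, treat regions as independent, and say nothing of the spread between animals or sorts. The functions were tested on simulated lists of the sizes of the SOX13hi and SOX13lo lists. Of 200 windows given extra regions among 25000 windows, 71% were recovered among the top 200 with a mean of 6 extra regions, and 92% with a mean of 10. The simulated regions were spread evenly at random, whereas some real windows were dense in all libraries. These recoveries may therefore not hold for the real lists. Alternatives were the upper 50% of each list by score, lists limited to the same number of highest-scoring peaks (33155, the shortest list), a reciprocal overlap of 50%, peak centres within 200 bp, and autosomes only. The reciprocal and centre rules cannot be applied to merged regions, so ratios and region counts were there taken on the peaks of each list. Joining neighbouring peaks within 150 bp was added after seeing the data.

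Peaks were not assigned to genes. The gene table at hand is of the GRCm38 assembly, whose coordinates differ from mm9, so promoter shares, the 12 gene lists and the 16 sequence motifs planned for these comparisons were not analysed here. The table was used only for the chromosome of Sox13 and Tcrb. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.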

Results

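Accessible chromatin was profiled in 5 libraries of mouse thymocytes, 1 per cell population. γδ T cells are T cells whose antigen receptor is built from γ and δ chains, and SOX13 is an HMG-box transcription factor of the SOX family. The SOX13hi and SOX13lo fractions of CD24+ γδ thymocytes were compared with each other, with the same fractions of animals that carried a Sox13 transgene, and with DP thymocytes, an intermediate stage of αβ T cell development. The SOX13hi list held 54435 peaks covering 5.24 Mb, and the SOX13lo list held 67482 peaks covering 7.13 Mb. The transgenic SOX13hi list held 63932 peaks over 5.86 Mb, the transgenic SOX13lo list 33155 peaks over 2.65 Mb, and the DP list 113877 peaks over 11.8 Mb. Peaks were short, with a median width of 30 bp in the transgenic SOX13lo list and 41 to 58 bp in the other lists. Between 42.1% and 50.2% of the peaks of each list were 28 to 30 bp wide. Merging the 5 lists gave 157434 regions. Of these, 14870 (9.45%) were present in all 5 libraries. No group has a replicate, so the differences below are between libraries.

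The first comparison asked how chromatin differs between γδ thymocytes sorted for high and for low to absent CFP. Most of the strong accessible sites were common to both fractions. Of the SOX13hi peaks, 62.7% (95% interval 62.3 to 63.1) met a SOX13lo peak, against 0.491% for randomly shifted peaks. Of the SOX13lo peaks, 46.4% (46.0 to 46.8) met a SOX13hi peak. Among the 25% of SOX13hi peaks with the highest scores, 91.1% were shared, and among the remaining SOX13hi peaks 53.2%. The peaks of SOX13hi that SOX13lo lacked had a median score of 9, close to the lowest score of that list (7), and the shared SOX13hi peaks had a median score of 18. In merged regions, 14532 were present in SOX13hi and absent from SOX13lo, and 29242 were present in SOX13lo and absent from SOX13hi. These numbers move with the length of the lists and with the overlap rule. With equal numbers of highest-scoring peaks, 67.0% of SOX13hi peaks and 61.9% of SOX13lo peaks were shared. With a reciprocal overlap of 50% the shares were 19.3% and 15.5%, and with peak centres within 200 bp 77.2% and 62.7%.

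The fractions were also compared in 100 kb windows. After scaling to equal totals, SOX13hi had at least 5 more regions than SOX13lo in 124 of 13752 windows and at least 5 fewer in 128. With lists of equal length these numbers were 31 and 37. The window with the largest deficit in SOX13hi was on chromosome 4 at 144800001 to 144900000 (mm9), with 27 regions in SOX13hi and 57 in SOX13lo. The next lay on chromosome 3 at 130800001 to 130900000. It held 5 regions in SOX13hi (exact Poisson interval 1.62 to 11.7) and 25 in SOX13lo (16.2 to 36.9). The 3 further windows were on chromosome 6 at 142800001 (8 against 25 regions), chromosome 11 at 22700001 (9 against 26) and chromosome 9 at 112100001 (10 against 27). DP cells had 61, 45, 51, 52 and 40 regions in these 5 windows, in the order given. The transgenic SOX13hi library had 26, 12, 14, 15 and 16 regions in them, and the transgenic SOX13lo library, whose list was the shortest, had 12, 5, 5, 7 and 9. With lists of equal length SOX13hi had 15, 3, 4, 8 and 6 regions in these windows and SOX13lo 27, 11, 12, 13 and 12. Transgenic SOX13hi then had 19, 5, 5, 8 and 8, close to transgenic SOX13lo in all but the first. DP then had 16, 13, 14, 12 and 12, close to SOX13lo in all but the first, where DP was lower.

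Windows with more regions in SOX13hi included chromosome 15 at 19700001 to 19800000, with 15 regions in SOX13hi (8.40 to 24.7) and 2 in SOX13lo (0.242 to 7.22). The transgenic SOX13hi library had 5 regions there, DP had 1 and transgenic SOX13lo had 0. On chromosome 14 at 24200001 to 24300000, SOX13hi had 13 regions and transgenic SOX13hi had 11, whereas SOX13lo had 4, transgenic SOX13lo 3 and DP 1. A window on chromosome 8 at 14900001 held 23 regions in SOX13hi, 17 in SOX13lo and 45 in DP. For SOX13hi against SOX13lo, lists of equal length gave 11 against 1 on chromosome 15, 6 against 1 on chromosome 14 and 11 against 9 on chromosome 8. DP then had 10 regions in the chromosome 8 window. The other 2 windows named by the rule, at 3000001 on chromosome 11 and at 3000001 on chromosome 9, were dense in all 5 libraries. They held 125 to 143 and 63 to 70 regions per library. Before scaling SOX13hi had fewer regions there than SOX13lo (128 against 142, and 66 against 68), and the scaled difference on chromosome 11 turned with lists of equal length.

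**Figure D1:**
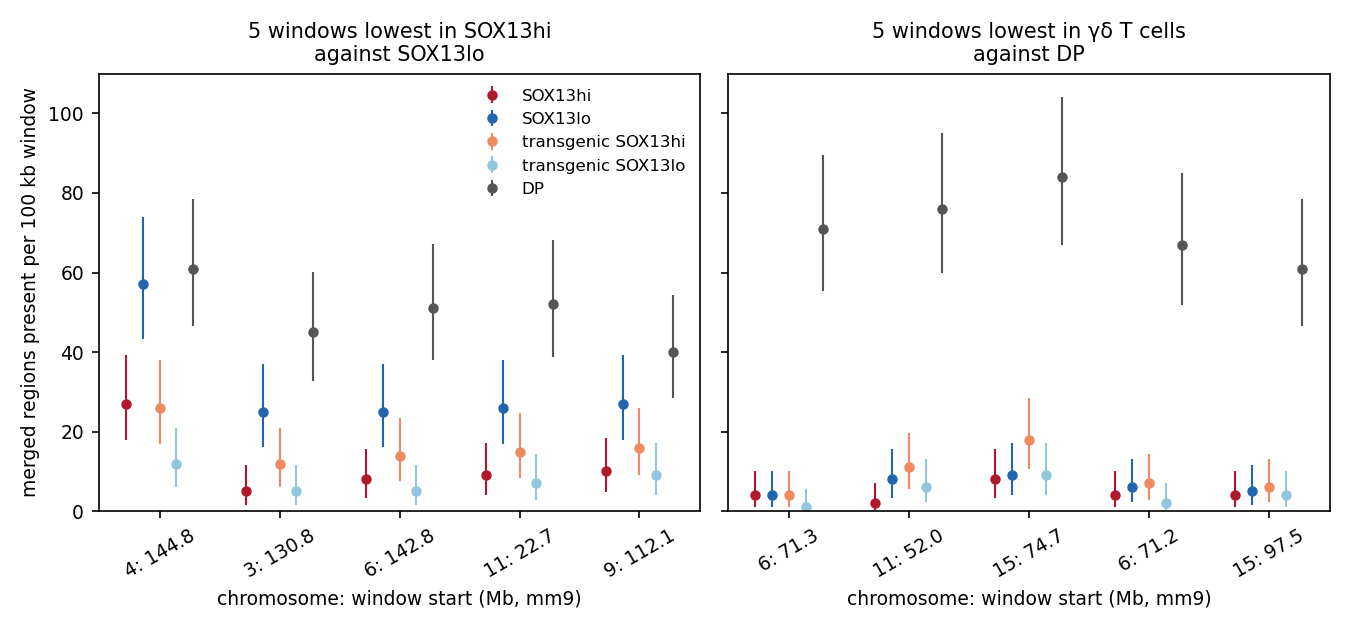
Number, not scaled to list length, of merged accessible regions present in each library (y axis, regions per 100 kb window) for the 5 windows with the largest deficit in SOX13hi against SOX13lo (left) and in γδ T cells against DP (right), each named by chromosome and window start in Mb on mm9. Points are single libraries and bars are exact Poisson 95% intervals for counting error. On the left SOX13lo had 25 to 57 regions and SOX13hi 5 to 27, and on the right DP had 61 to 84 regions against 1 to 18 in any γδ library.

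In cells with the Sox13 transgene, most of the highest-scoring peaks of each fraction were shared with the other. Of the transgenic SOX13lo peaks, 67.3% (66.8 to 67.8) met a transgenic SOX13hi peak, and of the transgenic SOX13hi peaks 31.2% (30.8 to 31.6) met a transgenic SOX13lo peak. The SOX13lo list was the shorter, and with equal numbers of highest-scoring peaks these shares were 59.4% and 51.3% (50.7 to 51.8). They were 17.7% and 9.20% with a reciprocal overlap of 50%, and 84.6% and 44.3% with peak centres within 200 bp. Among the 25% of peaks with the highest scores, 91.6% of transgenic SOX13lo peaks and 74.3% of transgenic SOX13hi peaks were shared. In merged regions, 33927 were present in transgenic SOX13hi and absent from transgenic SOX13lo, and 5660 the other way round.

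The window differences of the non-transgenic fractions were then looked up in the transgenic pair, which shares no library with them. Windows dense in all 5 libraries (20 or more regions in each, 6 windows with all peaks and 2 with lists of equal length) were left out. Of the 122 windows with at least 5 more regions in SOX13hi, 80 (65.6%, 56.4 to 73.9) also had more regions in transgenic SOX13hi than in transgenic SOX13lo after scaling. Of the 128 windows with at least 5 more in SOX13lo, 60 (46.9%, 38.0 to 55.9) did. In 2564 windows with a scaled difference under 1 region and at least 6 regions in SOX13hi and SOX13lo together, the share was 45.3% (43.3 to 47.2). With lists of equal length the 3 shares were 74.2% of 31 windows, 43.2% of 37 windows and 49.6% of 1794 windows.

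A further question was which of the fraction-specific regions were present in transgenic cells. Transgenic SOX13hi held 31.6% (30.8 to 32.4) of the 14532 regions that only SOX13hi had of the non-transgenic fractions, and 22.2% (21.7 to 22.6) of the 29242 that only SOX13lo had. The ratio of these shares was 1.43 (1.38 to 1.47). Transgenic SOX13lo held 8.18% (7.73 to 8.63) of the SOX13hi-only and 7.61% (7.30 to 7.92) of the SOX13lo-only regions, a ratio of 1.07 (1.00 to 1.15). DP held 32.7% of the SOX13hi-only and 39.1% of the SOX13lo-only regions, a ratio of 0.836 (0.814 to 0.860). The ratio stayed above 1 in transgenic SOX13hi and below 1 in DP under each of the 6 alternative settings. In transgenic SOX13lo it was 0.892 with equal numbers of highest-scoring peaks, so its direction depended on the setting. Under the reciprocal and centre rules the ratio was taken on the peaks of each list instead of merged regions. There a SOX13hi-only peak can still overlap a SOX13lo peak in part. With a reciprocal overlap of 50% the ratio was 1.56 in transgenic SOX13lo, above the 1.32 in transgenic SOX13hi. With peak centres within 200 bp the 2 ratios were 1.46 and 1.53.

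**Figure D2:**
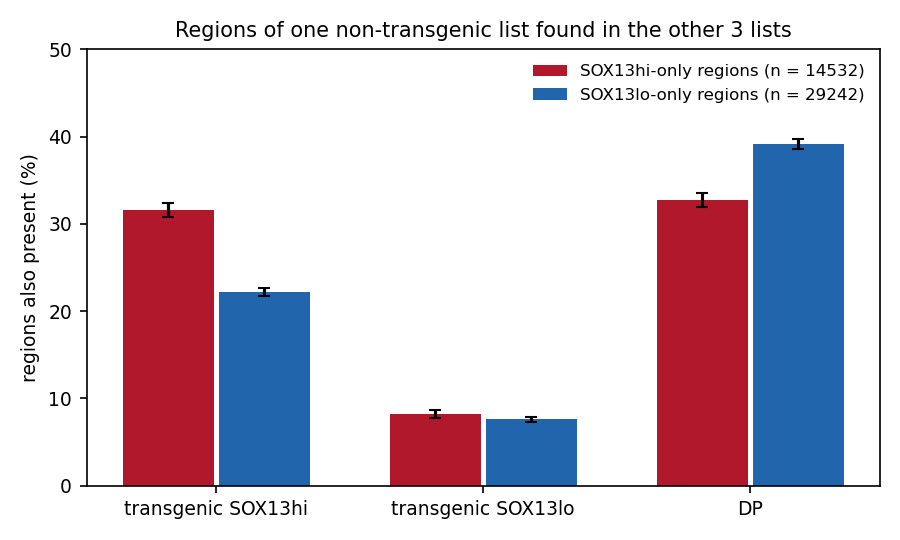
Percent of SOX13hi-only regions (red) and SOX13lo-only regions (blue) that were also present in the transgenic SOX13hi, transgenic SOX13lo and DP libraries (y axis, percent of regions). Bars are single libraries with exact 95% intervals for counting error. Transgenic SOX13hi held 31.6% and 22.2% of them, and DP held 32.7% and 39.1%.

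The 5 windows with the largest excess in transgenic SOX13hi over SOX13hi were on chromosomes X and Y. On chromosome Y at 2800001 to 2900000, transgenic SOX13hi had 114 regions and transgenic SOX13lo 101, against 24 in SOX13hi and 28 in SOX13lo. On chromosome Y at 1700001 to 1800000 the numbers were 27 and 17 against 0 and 2. The window on chromosome Y at 2700001 held 40 and 33 regions against 10 and 17. On chromosome X at 121200001 there were 24 and 17 regions against 0 and 1, and at 120100001 there were 26 and 25 against 2 and 3. DP, whose list was the longest, had 121, 28, 40, 20 and 21 regions in these 5 windows. In lists of equal length DP had 39, 2, 16, 0 and 0, transgenic SOX13hi had 92, 13, 31, 5 and 13, and transgenic SOX13lo had 102, 18, 33, 17 and 25. SOX13hi then had 12, 0, 9, 0 and 0 regions and SOX13lo 8, 0, 8, 0 and 0. In the opposite direction, the window on chromosome X at 47900001 to 48000000 held 40 regions in SOX13hi (28.6 to 54.5) and 47 in SOX13lo (34.5 to 62.5). It held 22 in transgenic SOX13hi (13.8 to 33.3), 10 in transgenic SOX13lo (4.80 to 18.4) and 5 in DP. Its equal-length values were 32, 26, 8, 10 and 2 regions, in the same order. Chromosome Y gave 1.47 and 1.45 of every 1000 peaks in SOX13hi and SOX13lo, 4.43 and 7.06 in the transgenic SOX13hi and SOX13lo lists, and 2.89 in DP. These rates were 1.33, 0.845, 5.85, 7.06 and 2.29 with lists of equal length. Chromosome X gave 24.7 and 24.3 of every 1000 peaks in SOX13hi and SOX13lo, and 23.3 and 22.7 in the transgenic lists.

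On autosomes, a window on chromosome 8 at 19900001 to 20000000 held 39 regions in transgenic SOX13lo, 20 in transgenic SOX13hi, 11 in SOX13lo, 3 in SOX13hi and 3 in DP. On chromosome 13 at 19400001 to 19500000 the 2 non-transgenic libraries had 33 and 39 regions, transgenic SOX13hi had 29 and transgenic SOX13lo had 7. The neighbouring window at 19300001 held 18 and 16 regions in SOX13hi and SOX13lo, and 11 and 4 in the transgenic fractions. The chromosome 15 window at 19700001, which had 15 regions in SOX13hi, had 5 in transgenic SOX13hi. The chromosome 4 window at 144800001, with 57 regions in SOX13lo, had 12 in transgenic SOX13lo. Windows on chromosome 6 at 114800001 and on chromosome 9 at 88200001 held 34 and 20 regions in SOX13lo and 6 and 1 in transgenic SOX13lo. The window at 166400001 on chromosome X held 39 regions in transgenic SOX13lo and 29 in SOX13lo. The transgenic SOX13lo list is the shortest, and with lists of equal length the differences from SOX13lo were smaller in several windows. SOX13lo and transgenic SOX13lo then had 27 and 12 regions in the chromosome 4 window, 12 and 7 at 19400001 on chromosome 13, 12 and 6 on chromosome 6, and 8 and 1 on chromosome 9. They had 2 and 39 in the chromosome 8 window and 15 and 39 at 166400001 on chromosome X. SOX13hi and transgenic SOX13hi had 15 and 12 at 19400001 and 6 and 4 at 19300001 on chromosome 13, and 11 and 4 on chromosome 15. The dense windows at 3000001 on chromosomes 11 and 9 were also among those with the largest excess in transgenic SOX13lo over SOX13lo, with 133 against 111 and 67 against 63 regions in lists of equal length. For transgenic SOX13hi against SOX13hi the chromosome 11 window was among the largest deficits after scaling (143 against 128 regions before it), and this direction turned with lists of equal length (122 against 102).

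**Figure D3:**
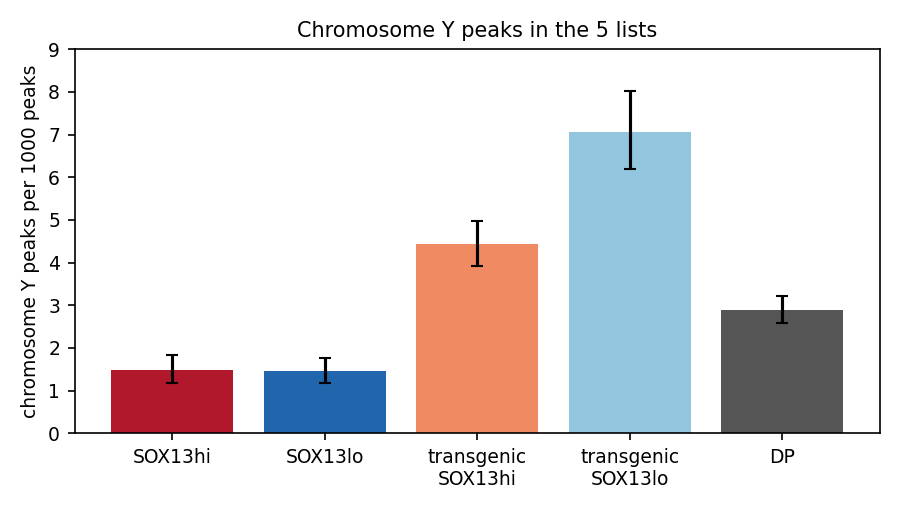
Chromosome Y peaks per 1000 peaks of each list (y axis) in the 5 libraries. Bars are single libraries with exact 95% intervals for counting error. The transgenic lists had 4.43 and 7.06, the non-transgenic γδ lists 1.47 and 1.45, and the DP list 2.89.

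A cluster of peaks on chromosome 1 at 135279404 to 135289718, chosen after its values were seen from regions that only the transgenic libraries held, was present in both transgenic lists with 12 peaks each. SOX13hi had 0 peaks there, SOX13lo 2 and DP 1. In transgenic SOX13lo the cluster included a peak of 644 bp with a score of 780, above 99.9% of the peaks in that list. In transgenic SOX13hi the highest-scoring peak of the cluster had a score of 59, above 89.8% of the peaks in that list.

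**Figure D4:**
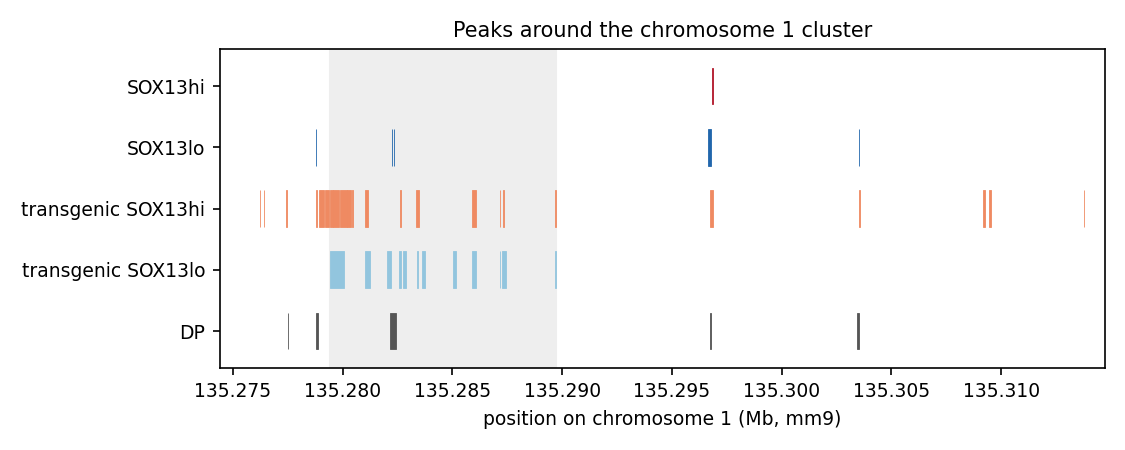
Peaks of the 5 libraries (rows) along chromosome 1 (x axis, position in Mb on mm9), drawn to scale with a thin outline so that the shortest stay visible. The grey band marks the cluster at 135279404 to 135289718, which held 12 peaks in each transgenic list and 0 to 2 in the others.

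The last comparison set γδ T cells against DP thymocytes. The DP list, the longest with 113877 peaks, held a large set of regions that no γδ list had. It also held nearly all regions that the γδ libraries had in common. Of the 15962 regions present in all 4 γδ libraries, 93.2% were also present in DP, and 1092 were absent from DP. Of the 93939 regions present in any γδ library, 49.8% were present in DP. The 47143 absent from DP included 37069 held by exactly 1 γδ library. In DP, 63495 regions were absent from all 4 γδ libraries. These DP regions had a median score of 7, close to the lowest score of that list (5). The DP regions that all 4 γδ libraries shared had a median score of 123. A region's score is the sum over its DP peaks, and a shared region can hold several, which widens this contrast. For single DP peaks the median score was 37 to 83 where they met a peak of a given γδ list. It was 8 to 9 where they did not. With the same number of highest-scoring peaks in every list, 8558 regions were in DP alone and 1454 were in all 4 γδ libraries and not in DP.

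The 5 windows with the largest DP excess were far above every γδ library. The window on chromosome 6 at 71300001 to 71400000 held 71 regions in DP (55.5 to 89.6) and 1 to 4 in the γδ libraries. Its neighbour at 71200001 held 67 in DP and 2 to 7 in the γδ libraries. On chromosome 11 at 52000001 to 52100000 DP had 76 regions (59.9 to 95.1), SOX13hi had 2, SOX13lo 8, transgenic SOX13hi 11 and transgenic SOX13lo 6. On chromosome 15 the windows at 74700001 and 97500001 held 84 and 61 regions in DP, and 8 to 18 and 4 to 6 in the γδ libraries. With lists of equal length all 5 windows kept their direction, with 11 to 20 regions in DP and at most 10 in a γδ library.

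The 5 windows with the largest γδ excess included 1 on chromosome 13 at 19400001 to 19500000 and 1 on chromosome X at 47900001 to 48000000. The chromosome 13 window held 33 regions in SOX13hi (22.7 to 46.3), 39 in SOX13lo (27.7 to 53.3), 29 in transgenic SOX13hi, 7 in transgenic SOX13lo and 16 in DP. It held 15, 12, 12, 7 and 3 with lists of equal length. The chromosome X window held 40, 47, 22 and 10 regions in the γδ libraries and 5 in DP. The non-transgenic γδ libraries thus lay above the transgenic ones there, and DP, from wild-type animals, was the lowest. The remaining windows named by the rule were those at 3000001 on chromosomes 11 and 9 and the chromosome Y window at 2800001. The chromosome 11 window had the largest scaled γδ excess. Before scaling it held 128, 142, 143 and 133 regions in the γδ libraries and 125 in DP, so it was dense in every library. With lists of equal length it held 102, 111, 122 and 133 regions in the γδ libraries and 20 in DP. The chromosome 9 window held 66 to 70 regions in the γδ libraries and 63 in DP before scaling. With lists of equal length it held 62 to 67 in the γδ libraries and 41 in DP. In that chromosome Y window the excess came from the transgenic libraries, since SOX13hi (12) and SOX13lo (8) lay below DP (39) with lists of equal length. DP came from wild-type animals and the γδ libraries from TCRbeta knockout animals, so cell type and genotype differed together. Only the DP list held mitochondrial peaks.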

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

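All tests in this part were chosen after the results were seen.

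The transgenic lists held 4.43 (transgenic SOX13hi) and 7.06 (transgenic SOX13lo) chromosome Y peaks per 1000 peaks, the non-transgenic γδ lists held 1.47 and 1.45, and DP, which carried no transgene, held 2.89. With lists of equal length the lower transgenic list (5.85) had 4.41 times the rate of the higher non-transgenic list (1.33), which argues against list length as the cause. A candidate explanation is that the pooled animals differed in sex between the genotypes, and over 3 blocks of chromosome Y the lower transgenic list exceeded the higher non-transgenic list by at least 2.17 times in peaks per 1000. The chromosome X windows at 121200001 (24 and 17 regions against 0 and 1) and 120100001 (26 and 25 against 2 and 3) were also higher in the transgenic lists. Whether a different sex make-up would give this was not tested. Chromosome X as a whole gave 23.3 and 22.7 peaks per 1000 against 24.7 and 24.3. With lists of equal length DP (2.29, 1.81 to 2.87) lay above SOX13hi (1.33, 0.964 to 1.78) and SOX13lo (0.845), so a difference in this rate also arose without the transgene, and sex cannot be told apart here from the mapping of repeated sequence or, for the transgenic lists, an effect of the transgene, which were not tested.

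A cluster of peaks on chromosome 1 at 135279404 to 135289718 was found in both transgenic lists, 12 peaks in each, against 0 in SOX13hi, 2 in SOX13lo and 1 in DP. It was chosen because its window held 8 autosomal regions present in both transgenic libraries and in none of the other 3, a number matched only by the chromosome 8 window at 19900001. The shortest list, transgenic SOX13lo, held 12 of these peaks. The choice required regions in both transgenic lists and in none of the other 3. This number therefore cannot decide on list length as the cause. The next 50 kb held 0 peaks of transgenic SOX13lo, 7 of transgenic SOX13hi, 1 of SOX13hi, 2 of SOX13lo and 3 of DP. A candidate source is DNA of the transgene itself: Sox13 is on chromosome 1 in the GRCm38 gene table, and 4.17% of the 24 transgenic peaks in the cluster met a peak of another genotype, against 83.4% of all peaks of those lists. The share is low partly by construction, since the cluster was chosen from regions the other lists lacked, an endogenous locus opened in transgenic cells would give it too, and the mm9 position of Sox13 was not used here, so the sources cannot be told apart.

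The SOX13hi list was 0.807 times as long as the SOX13lo list in non-transgenic cells and 1.93 times as long in transgenic cells. The opposite directions were not tested, with 1 library each. The DP list held 7 mitochondrial peaks and the γδ lists held 0.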

How the results depend on the processing

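The 5 lists contain no touching peaks, so merging those changed no list length, and joining peaks within 150 bp (added after seeing the data) kept every list within 1.5 times its length. Of 64 recomputed values, 27 stayed within their counting interval or within 1.5 times, 34 moved beyond it and 3 changed direction, all 3 of them the ratio in transgenic SOX13lo. Sharing is given below in the order SOX13hi in SOX13lo, SOX13lo in SOX13hi, transgenic SOX13hi in transgenic SOX13lo, and the converse (62.7%, 46.4%, 31.2% and 67.3% with all peaks). Ratios are SOX13hi-only over SOX13lo-only shares (1.43 in transgenic SOX13hi, 1.07 in transgenic SOX13lo, 0.836 in DP). They were taken on merged regions, or on the peaks of each list with a reciprocal overlap and with peak centres within 200 bp. With the upper 50% of each list by score, sharing was 73.6%, 56.0%, 37.6% and 77.9%, the ratios were 1.59, 0.991 and 0.813, and 570 regions were in all γδ libraries but not DP and 27897 in DP alone. With equal numbers of highest-scoring peaks, sharing was 67.0%, 61.9%, 51.3% and 59.4%, the ratio was 0.892 in transgenic SOX13lo and 0.809 in DP, and 8558 regions were in DP alone. With a reciprocal overlap of 50%, sharing was 19.3%, 15.5%, 9.20% and 17.7%, the ratios were 1.32 and 1.56 in the transgenic SOX13hi and SOX13lo libraries, and 727 SOX13hi peaks were in all γδ lists but not DP. With peak centres within 200 bp, sharing was 77.2%, 62.7%, 44.3% and 84.6%, the ratios were 1.53, 1.46 and 0.862, and 3265 SOX13hi peaks were in all γδ lists but not DP. With peaks within 150 bp joined, sharing was 68.3%, 53.4%, 36.5% and 73.5%, the ratio in transgenic SOX13lo was 0.878, and 711 regions were in all γδ libraries but not DP. Autosomes alone moved no value beyond its interval. The causes of the moves and reversals were not tested. Of the 5 windows per direction, 1 and 1 (higher and lower in SOX13hi against SOX13lo) and 4 and 0 (γδ against DP) were again among the top 5 with lists of equal length. Promoter shares, gene spans, gene lists and motifs were not run, since no annotation or sequence of mm9 was used. Read depth is unknown, so a region absent from a list is one not called at that list's threshold, and regions near the lowest scores decide most of the library-specific numbers.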

Other observations

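All tests and regions in this part were chosen after the results were seen.

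The strongest fraction-specific sites were few. After joining peaks within 150 bp, 5739 of 40308 SOX13hi clusters (14.2%) had no SOX13lo peak within 500 bp, and 7 of them were in the top 10% of that list by score. Of 48963 SOX13lo clusters, 12934 (26.4%) had no SOX13hi peak within 500 bp, and 5 were in the top 10%. SOX13hi clusters that transgenic SOX13hi shared and that both SOX13lo lists and DP lacked numbered 818. The highest-scoring were on chromosome 3 at 67240028 to 67240090 (63 bp, score 108), chromosome 11 at 10445981 to 10446705 (score 102) and chromosome 1 at 146778422 to 146778980 (score 92). SOX13lo clusters that transgenic SOX13lo shared and that both SOX13hi lists lacked numbered 347, led by chromosome 10 at 17707664 to 17708272 (score 95) and chromosome 17 at 68353151 to 68353665 (score 89). DP was not considered for the latter.

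Sites found in every γδ library and absent from DP were also few, and strong ones were no more frequent among them than in the whole SOX13hi list. Of 433 SOX13hi clusters of this kind, 37 were in the top 10% of the list by score, which held 4048 of all 40308 clusters. The highest were on chromosome 3 at 141441235 to 141442342 (1108 bp, score 251) and chromosome 14 at 87046461 to 87046718 (score 236). The strongest DP clusters with no γδ peak within 500 bp, mitochondrial peaks aside, were on chromosome 1 at 186234395 to 186235822 (1428 bp, score 515) and chromosome 3 at 50246540 to 50246668 (score 378).

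A hypothesis from the sharing of regions is that part of the difference between SOX13hi and SOX13lo cells is also present in transgenic SOX13hi cells. There the ratio of SOX13hi-only to SOX13lo-only shares was 1.43 with lists of equal length (1.37 to 1.49), which argues against list length as its whole cause. Score floors were not matched, since scores were not compared between lists. In the converse comparison, of regions in transgenic SOX13hi only against transgenic SOX13lo only, the ratio of shares was 2.01 in SOX13hi, 1.52 in SOX13lo and 1.43 in DP, so there a ratio above 1 was not particular to the SOX13hi fraction. The name fields of the SOX13lo and SOX13hi lists both read SOX13hi, which an exchange of these lists alone would not give. Whether both lists came from SOX13hi cells was not tested. An exchange of the non-transgenic lists would put the ratio of transgenic SOX13hi below that of transgenic SOX13lo. The first was 1.33 times the second with all peaks and 0.848 to 1.63 times over 7 settings, below 1 with a reciprocal overlap alone. That setting used the peaks of each list and not merged regions, so it is not the same measure. Of the window shares, that of windows higher in SOX13hi (65.6%) ran in the labelled order. That of windows higher in SOX13lo (46.9%) was close to the 45.3% of windows with a scaled difference under 1 region. With 1 library per group and a direction that turned when the overlap rule and the measure changed, an exchange cannot be told apart from the labelled order.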
